A study of Drosophila melanogaster with 51 samples.

How the data were processed

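RNA of mutant Drosophila larvae and of wild-type larvae of the same age was extracted with TRIZOL, labelled with Cy3 and Cy5 after amino-allyl incorporation and hybridised together to 2-colour arrays, per the labels. The labels give 4 genotypes at 60, 72 and 96 h after egg deposition, with dye reversals, and thus 12 groups with 51 arrays. The values used are those of the table the authors deposited, taken as log2 ratios of the 2 channels, with 6621 entries. How background, normalization and filtering were done is not given in the sources used here. The array medians lay between -0.02 and 0.01, so the arrays look centred, and the SD of the values on an array lay between 0.344 and 0.946. The base of the logarithm is not stated. With the largest absolute value at 10.4, a base of 10 was excluded as giving ratios no scanner measures, while a natural logarithm was not excluded. It would make each log2 value larger by one common factor and leave the tests as they are. Between 5780 and 6561 entries had a value on an array, and signal over background was not used here because the table holds ratios alone.

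The direction of the ratios is not stated either. Of 53 pairs of arrays of one group with opposite dyes 47 correlated above 0.4 and 6 below 0.2, all 6 in csn5null, so the deposited ratios run one way whatever the dye. CSN4 and CSN5 were above 0 in their own nulls as deposited, so every sign was turned to give mutant over wild type, as the likely direction.

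Of the entries, 5072 had 1 gene symbol, 176 several and 1373 none listed, controls included. The symbols come from the platform annotation, and 4993 of the entries with 1 symbol were matched to the RefSeq gene table of the assembly Release 6 plus ISO1 MT, which was used for names and for which genes neighbour each other. The 32 control entries were left out of the tests, and 28 entries had no value on any array. Entries of one gene were averaged on each array (324 genes had more than 1), which left 6187 features, 4698 named and 1489 unnamed. Unnamed features were counted and not named. A feature was tested in a comparison if each group had a value on at least 2 arrays.

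The comparisons were each mutant against wild type, csn4null against csn5null, csn51 against csn53 and csn5null against the mean of csn51 and csn53 at each age, and 96 h against 60 h in each genotype. They were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 12 group coefficients and 1 dye coefficient per gene over all arrays, lmFit and eBayes (prior df 3.34, prior SD 0.235, median residual SD 0.257). Adjusted p-values are Benjamini-Hochberg values over the features of a comparison, with a threshold of 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Gene lists were tested with limma's cameraPR against all tested named genes, with a preset correlation between genes of 0.01, adjusted over lists and groups, for lists with at least 3 measured genes. Ecdysteroid synthesis (1 gene measured), salivary gland glue and intermoult (0) and larval serum and fat body storage proteins (1) were therefore not tested. Pearson's r and counts of shared calls describe the overlap between genotypes, beside the count that independent lists of those sizes would share.

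The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes CSN4 and CSN5, the 4 named genes with the largest rise and fall per group whose arrays all had that sign, the 3 largest each way per difference, and up to 4 members per list by adjusted p. Text examples were taken from these. The fit was tested on simulated data, where for csn51 minus csn53 at 72 h it recovered 17 of 50 genes changed by 0.5, 41 of 50 changed by 1 and all 50 changed by 3 on the log2 scale, among 6183 genes, with 4.94% of its calls false. In csn4null at 96 h, among 6186 genes, 15 calls (7.94%) were false, above the threshold of 5%. The simulated noise was normal and independent between genes, with the same SD of a gene on every array. It held no correlated genes and no arrays that stand apart, so these rates are not the error rates of the real calls. The alternatives were no dye term, only the arrays of the groups compared together with no dye term (called a fit of its own arrays), arrays centred on their medians, arrays scaled to one median absolute value by limma's scale method, a value on every array, each entry on its own, array weights, arrays of one age and number as a random block, each array left out in turn, and for lists a correlation estimated from the residuals. Fits without 2 or 3 doubted csn5null arrays were added after the data were seen.

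The replicate numbers in the labels were checked for pairing by correlating residuals of arrays with the same age and number. Of 18 pairs of genotypes at an age, 1 had every r above 0.1, csn4null and csn5null at 96 h, with 4 pairs between 0.108 and 0.156. Over all 71 pairs r lay between -0.569 and 0.580. That pairing comes from the data, since the labels do not say what a number marks.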

Results

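The COP9 signalosome is a conserved protein complex that removes the ubiquitin-like protein Nedd8 from cullins, the scaffolds of a large class of ubiquitin ligases, and its subunit CSN5 carries the catalytic site. Gene expression was measured in Drosophila melanogaster larvae with a null allele of CSN4 (csn4null), a null allele of CSN5 (csn5null) or one of 2 other alleles that by their names are CSN5 alleles (csn51 and csn53). Larvae were taken at 60, 72 and 96 h after egg deposition. Each of 51 arrays compared mutant RNA in one dye with RNA of wild-type larvae of the same age in the other. Whether larvae of one age were at the same stage of development was not measured here. A difference in timing from wild type therefore stays open for the changes given below. At 60, 72 and 96 h there were 3, 4 and 4 arrays of csn4null, 5, 4 and 4 of csn5null, 4, 4 and 5 of csn51, and 5, 4 and 5 of csn53. The deposited table held values for between 5780 and 6561 entries per array, and the number of arrays limits the precision. The labels describe the arrays of a group as biological repeats, and p-values measure only the spread between these samples. The fit of all arrays takes one spread per gene from all 51 arrays. A standard error or p-value can therefore miss a wide spread within its own group, or carry the spread of other groups.

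All values are log2 ratios of mutant over wild type, with standard errors of the fit. The n given with a gene is the number of arrays in its group. A gene can lack a value on some of them, which widens its standard error. The direction of the deposited ratios was not given in the sources used here. It was taken from the targets, whose deposited mean was 2.34 for CSN4 in csn4null and 3.23 for CSN5 in csn5null, so that mutant over wild type is the likely direction after every sign was turned. If that is wrong, every rise given here is a fall. The direction of CSN4 and CSN5 in their own nulls is therefore no independent result, but their size and their difference from the other genotypes are.

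CSN4 was lower in csn4null by a similar amount at every age. CSN4 was at -2.39 ± 0.17 (SE, n = 3) at 60 h, -2.47 ± 0.15 (n = 4) at 72 h and -2.19 ± 0.15 (n = 4) at 96 h. The limma adjusted p-values were 2.1e-14, 8.8e-17 and 1.5e-15, and every array showed the fall. CSN5 in csn5null was lower at -4.45 ± 0.30 (n = 5) at 60 h, -2.94 ± 0.33 (n = 4) at 72 h and -2.03 ± 0.33 (n = 4) at 96 h, with adjusted p-values of 1.3e-14, 3.5e-08 and 2.0e-05. In csn51 and csn53 neither gene passed the test in the fit of all arrays, where CSN5 lay between -0.53 and 0.25 and CSN4 between -0.21 and 0.30. CSN5 was lower in csn5null than in the mean of csn51 and csn53 at each age, by -3.95, -2.96 and -1.76, with adjusted p-values of 6.1e-11, 3.3e-07 and 0.000523. The arrays labelled csn5null 72 h replicate 3 and csn5null 96 h replicate 3 had CSN5 values of -0.32 and -0.01, against -3.44 or lower on the other 72 h arrays and -1.16 or lower on the other 96 h arrays. On the former, different entries of one gene correlated at -0.0455, against 0.244 or more on the 49 arrays other than these 2. In a fit of its own arrays, which here and throughout had no dye term, CSN5 did not pass the test in csn5null at 72 h (adjusted p = 0.154) or 96 h (adjusted p = 0.105).

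Other settings called CSN5 lower in csn53 and csn51 at 60 h, where it was at -0.53 (adjusted p = 0.133) and -0.47 (adjusted p = 0.252) in the fit of all arrays. The spread of CSN5 in that fit includes the 2 csn5null arrays whose CSN5 was near 0. In csn53 the adjusted p was 0.000447 in a fit of its own arrays, 0.00213 with array weights, 0.0064 without the 2 csn5null arrays whose CSN5 was near 0, and 0.00552 without these and csn5null 60 h replicate 5. In csn51 it was 0.00714, 0.0479, 0.0249 and 0.0229 under these settings. Fits of their own arrays also called CSN5 lower at 96 h in csn51 (-0.25, adjusted p = 0.0474) and csn53 (-0.21, adjusted p = 0.0208). They called CSN4 lower in csn53 at 60 h (-0.22, adjusted p = 0.00523) and higher in csn51 at 72 h (0.28, adjusted p = 0.0447), and array weights also called it in csn53 at 60 h (adjusted p = 0.0266).

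**Figure D1:**
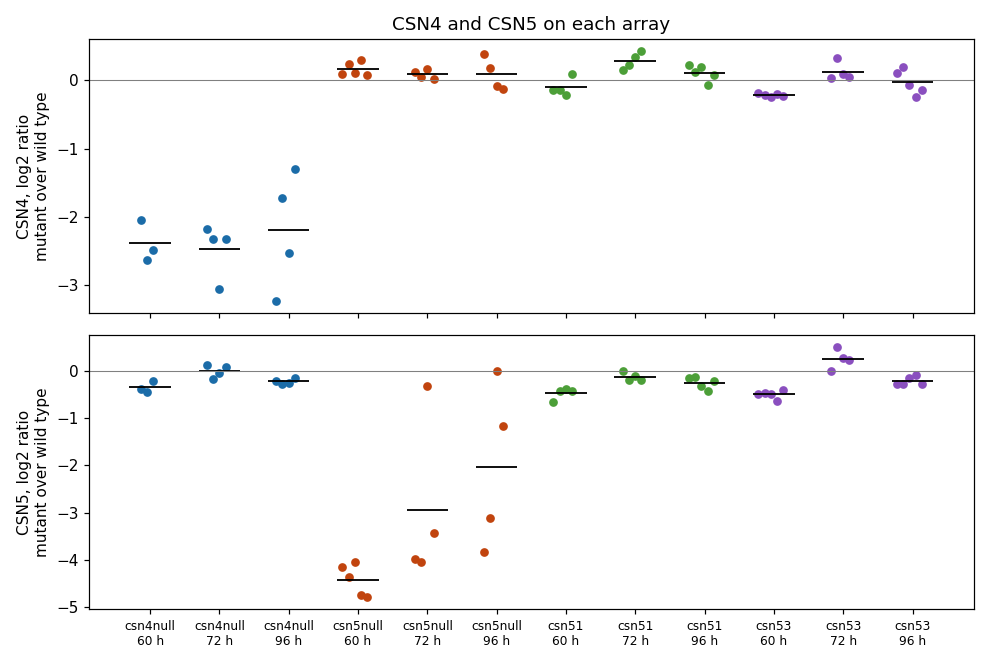
Log2 ratio of mutant over wild type of CSN4 and CSN5 on each array (points), with the mean of the arrays as a line, by genotype and age in h. CSN4 is low in csn4null, with fitted group values of -2.39, -2.47 and -2.19, and CSN5 in csn5null, with -4.45, -2.94 and -2.03, except on 1 array each at 72 and 96 h.

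In csn4null, Cyp6w1 rose at 60 h and Cyp6a8 at 60 and 72 h. Cyp28a5 and Arc1 fell at every age, and Fbp2, PPO1, PPO2 and PPO3 fell at 96 h. Cyp6w1 and Cyp6a8, both cytochrome P450 genes, rose at 60 h by 4.49 ± 0.25 and 4.04 ± 0.57 (n = 3), and eIF4E3, a translation initiation factor gene, by 3.47 ± 0.42. Cyp28a5, another cytochrome P450 gene, fell to -3.26 ± 0.30 at 60 h, -4.04 ± 0.26 at 72 h and -4.77 ± 0.26 at 96 h. Arc1, whose protein forms virus-like capsids that carry RNA, fell to -3.63 ± 0.28, -4.03 ± 0.24 and -3.65 ± 0.24 at these ages. Usp14, a proteasome-associated ubiquitin protease gene, fell by 2.86 ± 0.29 at 60 h and 3.30 ± 0.25 at 72 h. At 72 h the ecdysone-inducible gene ImpL1 rose by 5.39 ± 0.73 (n = 4) and CG4229 fell by 3.31 ± 0.49. At 96 h the cuticle protein gene TwdlL rose by 5.34 ± 0.47 and Amyrel, an amylase-related gene, by 3.78 ± 0.44. The fat body protein gene Fbp2 fell by 7.61 ± 0.67, and the prophenoloxidase genes PPO1, PPO2 and PPO3, which act in melanization, by 3.46 ± 0.21, 2.91 ± 0.19 and 2.68 ± 0.20. The limma adjusted p of these changes was at most 2.7e-06, for Cyp6a8 at 60 h, and each change had the same sign on every array of its group. Cyp6a8 also passed the test at 72 h, at 5.45 on replicate 2 and 5.60 or more on the other arrays. Rdh1 was higher at 96 h, at 3.41 on replicate 2 and 4.08 or more on the others, and passed the test too.

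Among the gene lists fixed before the data were examined, proteasome genes were lower in csn4null at 60 and 96 h but not at 72 h. Of 16 measured members of the 26S proteasome, 9 fell at 60 h (10 adjusted over the list alone) and none rose, with a median of -0.29 and adjusted p = 0.000177 for the list, against adjusted p = 0.348 with an estimated correlation. At 96 h 10 fell (10 adjusted over the list alone), among them Prosbeta6 by 0.50 ± 0.09 and Rpt2 by 0.47 ± 0.09, with adjusted p = 0.00216 for the list and adjusted p = 0.457 with an estimated correlation. At 72 h 3 members were higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.18, adjusted p = 0.0527 for the list and adjusted p = 0.664 with an estimated correlation. The list was called higher there without a dye term (adjusted p = 0.0494), after scaling (0.0456), with array weights (0.0434) and without 2 or 3 csn5null arrays (0.0248 and 0.027), and not in a fit of its own arrays (0.238). Mitochondrial ribosomal protein genes were lower at the first 2 ages. Of 18 members 9 fell at 60 h (11 adjusted over the list alone), with adjusted p = 0.0007 for the list and adjusted p = 0.571 with an estimated correlation, and 14 fell at 72 h (14 adjusted over the list alone), with adjusted p = 5.0e-06 and adjusted p = 0.348 with an estimated correlation. mRpL15 fell by 0.66 ± 0.10 at 72 h. Of 15 oxidative phosphorylation genes 6 fell at 72 h (8 adjusted over the list alone; adjusted p = 0.0181 for the list, adjusted p = 0.605 with an estimated correlation). At 96 h 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.00216, adjusted p = 0.41 with an estimated correlation). Of 9 muscle genes 4 rose at 60 h (6 adjusted over the list alone; adjusted p = 0.00949, adjusted p = 0.41 with an estimated correlation).

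At 96 h 4 further lists moved in csn4null. Heat shock and chaperone genes rose in 4 of 8 members (5 adjusted over the list alone; adjusted p = 0.0268, adjusted p = 0.511 with an estimated correlation), among them the mitochondrial chaperone genes Hsc70-5 by 0.97 ± 0.14 and Hsp60A by 0.88 ± 0.16. DNA damage response and repair genes rose in 4 of 8 members (4 adjusted over the list alone; adjusted p = 0.0322, adjusted p = 0.348 with an estimated correlation). Midgut digestive enzyme genes fell in 3 of 5 members (3 adjusted over the list alone; adjusted p = 0.00579, adjusted p = 0.24 with an estimated correlation), with Mal-A5, a maltase gene, lower by -2.16 ± 0.16. Of 9 haemocyte and melanization genes 3 rose and 3 fell (3 and 3 adjusted over the list alone). That list was called lower with adjusted p = 0.0315 (adjusted p = 0.41 with an estimated correlation) although its median was 0.16, and the 3 members that fell were the prophenoloxidase genes. The COP9 subunit list was called lower at 60 h (adjusted p = 0.00103, adjusted p = 0.00709 with an estimated correlation) and at 96 h (adjusted p = 0.0397, adjusted p = 0.122 with an estimated correlation), and CSN4 was its 1 member of 5 past the test over all genes at each age (2 and 1 lower adjusted over the list alone). CSN4 is the mutated gene and was used to set the direction of the ratios, so these calls are no independent result. The list was not tested without CSN4.

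The test found 573 features higher and 474 lower in csn4null at 60 h, 781 and 767 at 72 h, and 932 and 1008 at 96 h. The 60 h count of 1047 was 470 without replicate 1 and 232 without replicate 2, and 78 in a fit of the 3 arrays alone, where Cyp6a8 (adjusted p = 0.0661) and eIF4E3 (adjusted p = 0.0519) were not called. In fits of their own arrays 1 of the 2 lists called at 72 h and 5 of the 7 called at 96 h were lost, and without the 2 csn5null arrays whose CSN5 was near 0 the DNA damage (adjusted p = 0.0524) and COP9 (adjusted p = 0.0687) lists at 96 h were lost and the immunity list was gained (adjusted p = 0.0246). Array weights ended the calls of the COP9 (adjusted p = 0.128), haemocyte (adjusted p = 0.058) and heat shock (adjusted p = 0.0504) lists at 96 h.

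**Figure D2:**
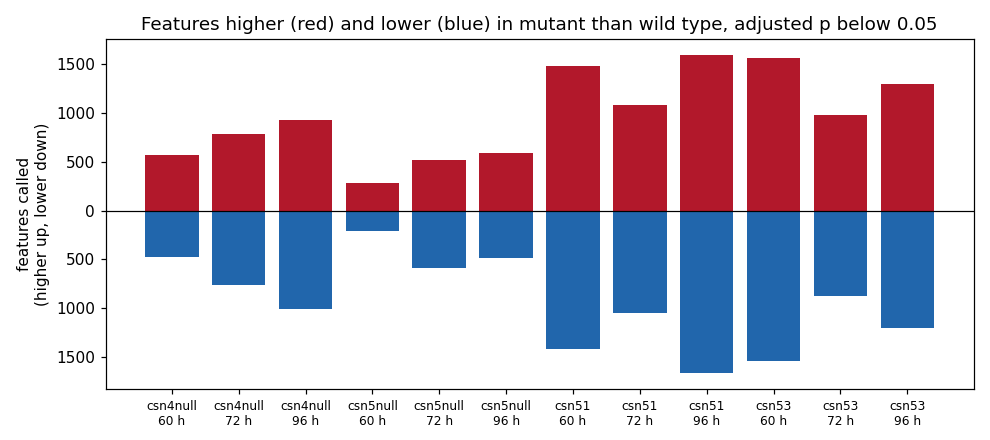
Number of features called higher (red, upward) and lower (blue, downward) in mutant than wild type by genotype and age in h, at an adjusted p below 0.05. Counts run from 491 in csn5null at 60 h to 3267 in csn51 at 96 h.

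In csn5null, Cyp6a8, Srg2 and GstZ1 rose at 60 h, and Fbp2, PPO1 and PPO2 fell at 96 h. At 60 h Cyp6a8 rose by 3.43 ± 0.36 (n = 5), Srg2 by 3.24 ± 0.39 and GstZ1, a glutathione transferase gene, by 2.18 ± 0.24, and mTerf3, a mitochondrial transcription factor gene, fell by 2.34 ± 0.21. At 72 h Sirup, a gene for an assembly factor of mitochondrial complex II, rose by 2.38 ± 0.55 (n = 4), and the cuticle protein gene Cpr67B fell by 1.79 ± 0.26 and Culd by 1.75 ± 0.30. At 96 h Srg2 rose by 3.64 ± 0.43 (n = 4), TwdlL by 3.26 ± 0.47 and Nepl11, a gene of the neprilysin-like family, by 2.25 ± 0.30. Fbp2 fell by 5.49 ± 0.67, PPO1 by 1.73 ± 0.21 and PPO2 by 1.35 ± 0.19. The limma adjusted p of these genes was at most 0.00214, for Sirup at 72 h. Scaling the arrays to one median absolute value moved Srg2 to 4.88, GstZ1 to 3.29 and mTerf3 to -3.63 at 60 h.

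Of 18 oxidative stress and detoxification genes 8 rose and 3 fell at 60 h (9 and 4 adjusted over the list alone), 8 and 2 at 72 h (10 and 3), and 9 and 1 at 96 h (10 and 1). The adjusted p of this list was 1.6e-05, 0.00234 and 3.2e-05, and with an estimated correlation the adjusted p was 0.0133, 0.122 and 0.0136. Cyp4e2, a cytochrome P450 gene, rose by 1.03 ± 0.09 (1.58 after scaling the arrays), 1.08 ± 0.11 and 1.08 ± 0.11, and Keap1, a regulator of the oxidative stress response, by 1.13 ± 0.15 at 96 h. Antimicrobial and humoral immunity genes rose in 4 of 6 members at 96 h (4 adjusted over the list alone; adjusted p = 0.0133, adjusted p = 0.122 with an estimated correlation), with Rel, a transcription factor of the immune response, higher by 1.39 ± 0.23 and between -0.17 and 2.15 on the single arrays. Midgut digestive enzyme genes fell in 3 of 5 members at 96 h (3 adjusted over the list alone; adjusted p = 0.000177, adjusted p = 0.0416 with an estimated correlation), Mal-A5 by 1.59 ± 0.16. Proteasome genes fell in 2 of 16 members (1 adjusted over the list alone; adjusted p = 0.0354, adjusted p = 0.648 with an estimated correlation) and oxidative phosphorylation genes in 3 of 15 at 96 h (3 lower and 1 higher adjusted over the list alone; adjusted p = 0.045, adjusted p = 0.648 with an estimated correlation). Neither of these lists was called in a fit of its own arrays (adjusted p = 0.0846 and 0.25), and scaling also ended the latter call (adjusted p = 0.119).

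At 60 h cell cycle and DNA replication genes rose in 4 of 21 members of csn5null (6 adjusted over the list alone; adjusted p = 0.0042, adjusted p = 0.605 with an estimated correlation), and the list was not called in a fit of its own arrays (adjusted p = 0.113). Its median was 0.18 in the group but -0.41 on replicate 5, against 0.31 or more on the other 4 arrays. At 72 h cytoplasmic ribosomal protein genes fell in 5 of 6 members (5 adjusted over the list alone; adjusted p = 0.00199, adjusted p = 0.0421 with an estimated correlation), with a median of -0.46 that was -0.20 without the 2 arrays whose CSN5 was near 0, where the list had adjusted p = 0.0556. It was also lost with array weights (adjusted p = 0.0846), without 3 csn5null arrays (0.051) and in a fit of its own arrays (0.0601). Mitochondrial ribosomal protein genes fell in 7 of 18 members (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.00579, adjusted p = 0.648 with an estimated correlation). The COP9 list was called lower at 60 h (adjusted p = 0.00317, adjusted p = 0.0136 with an estimated correlation), where CSN5 was its 1 member past the test (1 adjusted over the list alone) while its median was 0.02, above 0, and at 72 h (adjusted p = 0.0354, adjusted p = 0.122 with an estimated correlation), where alien, the gene of subunit CSN2, also fell by 0.37 ± 0.09 (2 lower adjusted over the list alone). The 72 h call was lost after scaling (adjusted p = 0.0765) and in a fit of its own arrays (0.246), where alien was not called either (0.17). The list holds the mutated gene CSN5 and was not tested without it, so neither call is independent of the target.

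The counts were 281 higher and 210 lower at 60 h, 515 and 584 at 72 h, and 586 and 482 at 96 h. The 60 h count of 491 was 886 without replicate 5, whose median correlation with the other arrays of its group was -0.02, and 301, 310, 311 and 300 without replicates 1, 2, 3 and 4. Replicate 5 correlated best, at 0.62, with csn53 60 h replicate 2, while its CSN5 was at -4.78 as in the rest of its group. The 96 h count of 1068 was 582, 582 and 598 without replicates 1, 2 and 4 and 1688 without the 3 doubted csn5null arrays together. Fitted on their own arrays the 72 and 96 h groups gave 1 and 39 calls, and there Sirup and Cpr67B (adjusted p = 0.144 each), Culd (0.15) and Cyp4e2 (0.116) at 72 h and Fbp2 (0.0606), Rel (0.0856), PPO1, PPO2, Keap1 and Cyp4e2 (0.0534 each) at 96 h were not called.

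In csn51, Rdh1 rose at 60 and 72 h, GstE1 was higher and CG13360 lower at every age, and Fbp2 fell at 96 h. Rdh1, a retinol dehydrogenase family gene, rose by 4.09 ± 0.28 at 60 h (n = 4) and 3.88 ± 0.28 at 72 h (n = 4). CG7724 rose by 3.89 ± 0.56 at 60 h and 5.35 ± 0.50 at 96 h (n = 5). GstE1, a glutathione transferase gene, rose by 2.65 ± 0.17, 1.66 ± 0.17 and 2.12 ± 0.15 at the 3 ages. Osi14 rose by 3.87 ± 0.81 at 60 h, the cuticle protein gene Cpr49Ae fell by 3.49 ± 0.35 at 72 h, and at 96 h TwdlL rose by 7.26 ± 0.42 and CG4229 by 5.91 ± 0.69. Yeast control entry 1, by its name no fly gene, had means of 0.18, -0.85 and 2.91 at the 3 ages, and entry 4 had 0.18, 0.23 and 0.45. Fbp2 fell by 8.10 ± 0.60 at 96 h, and CG13360 was at -2.91 ± 0.43, -3.72 ± 0.38 and -5.67 ± 0.34 at the 3 ages. CARPB, a carbonic anhydrase-related gene, fell by 5.47 ± 0.44 at 96 h. The limma adjusted p of these genes was at most 0.000133, for Osi14 at 60 h.

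DNA damage response and repair genes were higher in csn51 at 72 h, and at 96 h with adjusted p = 0.0655 with an estimated correlation. At 72 h 6 of 8 members rose (6 higher and 1 lower adjusted over the list alone), with a median of 0.86, adjusted p = 3.4e-06 and adjusted p = 0.00709 with an estimated correlation. The genes mre11, rad50 and nbs, whose products form a complex that binds broken DNA ends, rose by 1.92 ± 0.20, 1.55 ± 0.12 and 1.01 ± 0.10, and Xpc, a nucleotide excision repair gene, by 1.27 ± 0.13. At 96 h 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.00081, adjusted p = 0.0655 with an estimated correlation), among them p53 by 0.91 ± 0.12. At 60 h autophagy genes rose in 8 of 11 members (8 adjusted over the list alone; adjusted p = 0.00151, adjusted p = 0.348 with an estimated correlation), Atg13 by 2.00 ± 0.19 and Atg9 by 1.46 ± 0.19. Haemocyte and melanization genes rose in 5 of 9 members at 60 h (5 adjusted over the list alone; adjusted p = 0.00949, adjusted p = 0.348 with an estimated correlation), with PPO2 higher by 1.59 ± 0.19. At 96 h PPO2 was lower by -1.31 ± 0.17. Cell cycle and DNA replication genes fell in 15 of 21 members at 60 h (15 lower and 1 higher adjusted over the list alone; adjusted p = 0.000177, adjusted p = 0.407 with an estimated correlation), Mcm2 by 0.95 ± 0.15 and Cdk2 by 0.90 ± 0.14. Proteasome genes fell in 12 of 16 members at 60 h (13 adjusted over the list alone; adjusted p = 0.000177, adjusted p = 0.348 with an estimated correlation). They fell in 12 members at 96 h too (13 adjusted over the list alone; adjusted p = 0.0268, adjusted p = 0.648 with an estimated correlation).

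Mitochondrial ribosomal protein genes were lower at 60 and 72 h and higher at 96 h in csn51. The change of the list between ages was not tested, and the correlation estimated for it was 0.472. Of 18 members 17 fell at 60 h (18 adjusted over the list alone; adjusted p = 4.2e-07, adjusted p = 0.348 with an estimated correlation), 12 fell at 72 h (14 adjusted over the list alone; adjusted p = 0.00103, adjusted p = 0.605 with an estimated correlation) and 15 rose at 96 h (15 adjusted over the list alone; adjusted p = 0.00103, adjusted p = 0.605 with an estimated correlation). Oxidative phosphorylation genes fell in 12 of 15 members at 72 h (13 adjusted over the list alone; adjusted p = 0.000145, adjusted p = 0.348 with an estimated correlation) and in 9 at 96 h (9 adjusted over the list alone; adjusted p = 0.0312, adjusted p = 0.643 with an estimated correlation). At 96 h midgut enzyme genes fell in 4 of 5 members (4 adjusted over the list alone; adjusted p = 0.016, adjusted p = 0.348 with an estimated correlation), with Amy-p, an amylase gene, lower by -2.96 ± 0.30. Muscle genes fell in 8 of 9 members (8 adjusted over the list alone; adjusted p = 0.0181, adjusted p = 0.475 with an estimated correlation). The counts in csn51 were 1488 higher and 1416 lower at 60 h, 1086 and 1048 at 72 h, and 1599 and 1668 at 96 h. Scaling the arrays to one median absolute value lowered CG4229 at 96 h to 3.89, and in a fit of their own arrays the muscle (adjusted p = 0.0727) and oxidative phosphorylation (adjusted p = 0.0821) lists at 96 h were not called.

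In csn53, TwdlL and CG4229 rose at 60 and 96 h and fell at 72 h, and Fbp2 was lower at 96 h. TwdlL rose by 4.58 ± 0.42 and CG4229 by 4.41 ± 0.44 at 60 h (n = 5), fell by 3.08 ± 0.47 and 3.17 ± 0.49 at 72 h (n = 4), and rose by 5.61 ± 0.47 and 6.01 ± 0.44 at 96 h (n = 5). Yeast control entry 1 had means of 0.74, -1.46 and 1.33 at these ages, and entry 4 had 0.06, -0.36 and 0.24. Cpr49Ae fell by 4.55 ± 0.35 at 72 h. CG8745 rose by 3.38 ± 0.34 and Cyp6a8 by 3.18 ± 0.40 at 72 h. Mettl2, a methyltransferase-like gene, fell by 2.12 ± 0.12 at 60 h. At 96 h Fbp2 was at -8.50 ± 0.60, CARPB at -4.26 ± 0.34 and Alp1, an alkaline phosphatase gene, at -3.70 ± 0.21. The limma adjusted p of these genes was at most 3.8e-06, for CG4229 at 72 h.

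Of 18 oxidative stress and detoxification genes 11 rose and 1 fell in csn53 at 60 h (13 and 1 adjusted over the list alone; adjusted p = 0.000187, adjusted p = 0.0384 with an estimated correlation), Cyp6a8 by 2.98 ± 0.36 and GstE1 by 2.73 ± 0.15. Autophagy genes rose in 9 of 11 members (9 adjusted over the list alone; adjusted p = 0.00216, adjusted p = 0.348 with an estimated correlation) and haemocyte and melanization genes in 5 of 9 (5 adjusted over the list alone; adjusted p = 0.0113, adjusted p = 0.348 with an estimated correlation). Cell cycle and DNA replication genes fell in 15 of 21 members (15 adjusted over the list alone; adjusted p = 0.000709, adjusted p = 0.453 with an estimated correlation) and proteasome genes in 11 of 16 (12 adjusted over the list alone; adjusted p = 0.000872, adjusted p = 0.41 with an estimated correlation). All 18 mitochondrial ribosomal protein genes fell at 60 h (18 adjusted over the list alone; adjusted p = 1.6e-05, adjusted p = 0.386 with an estimated correlation), and 14 rose at 96 h (14 adjusted over the list alone; adjusted p = 0.000177, adjusted p = 0.457 with an estimated correlation). mRpL1 rose by 0.64 ± 0.07 at 96 h.

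At 72 h DNA damage response and repair genes rose in 4 of 8 members of csn53 (5 adjusted over the list alone; adjusted p = 0.0029, adjusted p = 0.125 with an estimated correlation), rad50 by 1.04 ± 0.12. Oxidative phosphorylation genes fell in 11 of 15 (14 adjusted over the list alone; adjusted p = 0.000531, adjusted p = 0.348 with an estimated correlation). Imaginal disc patterning genes fell in 5 of 6 (5 adjusted over the list alone; adjusted p = 0.00731, adjusted p = 0.0359 with an estimated correlation), ap, a wing selector gene, by 1.10 ± 0.13. Larval cuticle genes fell in 2 of 4 (2 adjusted over the list alone; adjusted p = 0.00216; no correlation was estimated for this list), and those were Cpr49Ae and kkv, a chitin synthase gene. At 96 h muscle genes fell in 8 of 9 members (8 adjusted over the list alone; adjusted p = 0.00278, adjusted p = 0.348 with an estimated correlation) and midgut enzyme genes in 3 of 5 (3 adjusted over the list alone; adjusted p = 0.0168, adjusted p = 0.348 with an estimated correlation). The counts were 1567 higher and 1541 lower at 60 h, 978 and 876 at 72 h, and 1298 and 1208 at 96 h. The 72 h count of 1854 was 959 in a fit of its own arrays, and the 96 h count of 2506 was 3789 with array weights.

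**Figure D3:**
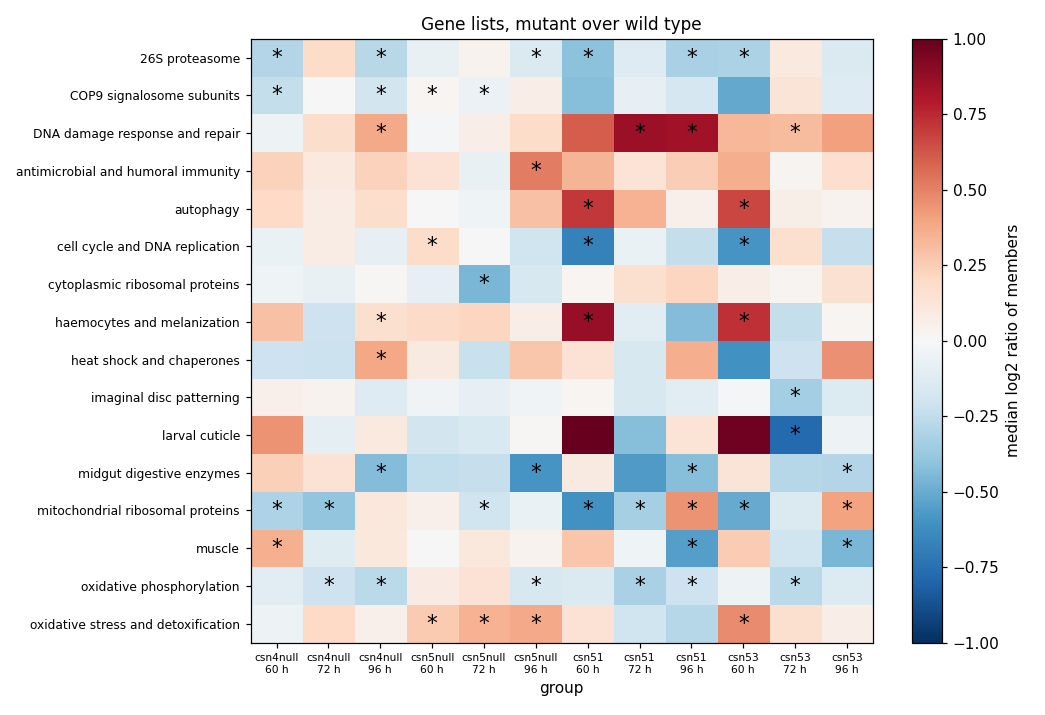
Median log2 ratio of mutant over wild type of each gene list called in at least 1 group (vertical) in each genotype and age in h (horizontal), with the colour scale ending at 1 in either direction and an asterisk where the list had an adjusted p below 0.05. Mitochondrial ribosomal protein genes have a median of -0.61 in csn51 at 60 h and 0.45 at 96 h.

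The 6 remaining lists were called in no group by camera in the fit of all arrays. The smallest adjusted p was 0.279 for cullin-RING ligase and Nedd8 pathway genes (csn51, 72 h), 0.143 for ecdysone response genes (csn5null, 72 h), 0.292 for programmed cell death genes (csn5null, 96 h), 0.0958 for insulin signalling and starvation genes (csn5null, 96 h), 0.27 for neuronal genes (csn51, 72 h) and 0.292 for testis genes (csn4null, 96 h). In fits of their own arrays the ecdysone list was called in csn4null at 72 h (median 0.13, adjusted p = 0.0452) and csn51 at 96 h (median 0.38, adjusted p = 0.0322). Its members moved in both directions. In csn51 at 96 h 5 of 10 rose and 3 fell (5 and 3 adjusted over the list alone), with the nuclear receptor gene Hr3 higher by 1.75 ± 0.24. Tested entry by entry, Hr3 reached 3.11 there. In csn53 at 60 h 2 of 10 cullin-RING and Nedd8 pathway genes rose and 5 fell (2 and 5 adjusted over the list alone), with Cul3 higher by 0.64 ± 0.09 and Cand1, a cullin-binding exchange factor gene, lower by -0.36 ± 0.08.

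Arc1, Usp14 and Nasp were lower in csn4null than in csn5null at every age. Arc1 was lower in csn4null than in csn5null by -3.58 ± 0.36 at 60 h, -4.79 ± 0.35 at 72 h and -4.20 ± 0.35 at 96 h, with limma adjusted p-values of 1.6e-09, 2.5e-13 and 5.1e-12. Usp14 was lower by -2.88 ± 0.36 at 60 h and -3.86 ± 0.35 at 72 h, and Nasp, a histone chaperone gene, by -3.82 ± 0.35 at 72 h and -3.94 ± 0.35 at 96 h. At the remaining age Usp14 was at -3.92 (96 h, adjusted p = 3.6e-11) and Nasp at -2.84 (60 h, adjusted p = 3.3e-07). At 96 h Cyp6w1 was higher by 3.28 ± 0.30 and Cyp28a5 lower by -4.64 ± 0.37. In all, 336 features were higher and 246 lower at 60 h, 376 and 279 at 72 h, and 109 and 195 at 96 h. The 60 h count of 582 was 238 and 150 without csn4null replicates 1 and 2, 259, 313, 337 and 349 without csn5null replicates 1, 2, 3 and 4, and 1375 without csn5null replicate 5. The 96 h count of 304 was 182 without csn4null replicate 3 and 200 and 201 without csn5null replicates 1 and 2.

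The alleles csn51 and csn53 differed in Rdh1 and Cyp6a8 at every age. Rdh1 was higher in csn51 by 3.25 ± 0.37, 3.28 ± 0.39 and 3.74 ± 0.35 at 60, 72 and 96 h, and Cyp6a8 was lower by -3.71 ± 0.54, -3.97 ± 0.57 and -3.30 ± 0.59. Both had an adjusted p from limma of at most 0.0003, the highest for Cyp6a8 at 96 h. CG9512 was higher by 1.89 ± 0.21 at 60 h and 1.66 ± 0.23 at 72 h. Counts were 5 higher and 7 lower at 60 h, 83 and 142 at 72 h, and 117 and 125 at 96 h. The 72 h count of 225 was 93 without csn51 replicate 4, 368, 130 and 62 without csn53 replicates 1, 3 and 4, and the 60 h count of 12 was 7 without csn51 replicate 3. With array weights the 3 counts were 42, 997 and 605, and in fits of their own arrays 7, 21 and 46. Without 2 csn5null arrays the 72 h count was 360, and without 3 the 72 and 96 h counts were 459 and 396. The 96 h count of 242 was 41 after scaling the arrays to one median absolute value, which also ended the difference of CG13360 (-3.02 ± 0.47 before, -1.36 after with adjusted p = 0.324). In fits of their own arrays CG9512 at 72 h was not called (adjusted p = 0.0589). Genetic background was not a factor in any comparison given here. The effect of an allele can therefore not be told apart from a difference in background.

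The null of CSN5 was compared with the mean of csn51 and csn53. At 60 h Osi14 was lower in csn5null by -5.69 ± 0.90 and CG12164 by -4.25 ± 0.75, while at 72 h CG12164 was higher by 4.18 ± 0.81, the cuticle protein gene TwdlW by 5.51 ± 0.95 and CG10814 by 4.87 ± 0.61. Cpr67B was lower by -3.91 ± 0.32 at 72 h. At 96 h Srg2 was higher by 4.56 ± 0.51 and CARPB by 3.75 ± 0.47, and ImpL1 was lower by -5.67 ± 0.95 and CG4229 by -5.58 ± 0.70. By limma the adjusted p of these differences was at most 0.000133, for CG12164 at 72 h. Counts were 1322 higher and 1383 lower at 60 h, 939 and 1006 at 72 h, and 952 and 858 at 96 h. Array weights raised the 60 h count of 2705 to 4190, and without csn5null replicate 5 it was 3080.

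Between 60 and 96 h the largest fall of a gene named by the rule in csn51, csn53 and csn5null was that of Fbp2, which was not tested in csn4null at 60 h and changed by -8.08 ± 0.90 in csn51, -8.48 ± 0.90 in csn53 and -5.34 ± 0.90 in csn5null. CARPB changed by -5.41 ± 0.69 in csn51 and -4.33 ± 0.48 in csn53. In csn4null PPO3 fell by 3.67 ± 0.31 and PPO1 by 3.22 ± 0.32, and in csn5null PPO1 fell by 2.15 ± 0.28. CG12009 rose by 4.78 ± 1.02 in csn51 and 5.05 ± 0.92 in csn53. The limma adjusted p was at most 0.000282, for CG12009 in csn51. CSN5 itself rose by 2.42 ± 0.44 in csn5null (adjusted p = 0.000428), a difference that includes the array labelled csn5null 96 h replicate 3 and was 4.56 after scaling the arrays. Counts were 337 higher and 393 lower in csn4null, 1019 and 1225 in csn51, 954 and 986 in csn53, and 229 and 227 in csn5null. The csn4null count of 730 was 444 and 401 without 60 h replicates 1 and 2 and 481 without 96 h replicate 3. The csn5null count of 456 was 296 and 953 without 60 h replicates 1 and 5, and 270, 251, 848 and 221 without 96 h replicates 1, 2, 3 and 4. In fits of the csn5null arrays alone neither Fbp2 (adjusted p = 0.053) nor CSN5 (adjusted p = 0.0752) was called.

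**Figure D4:**
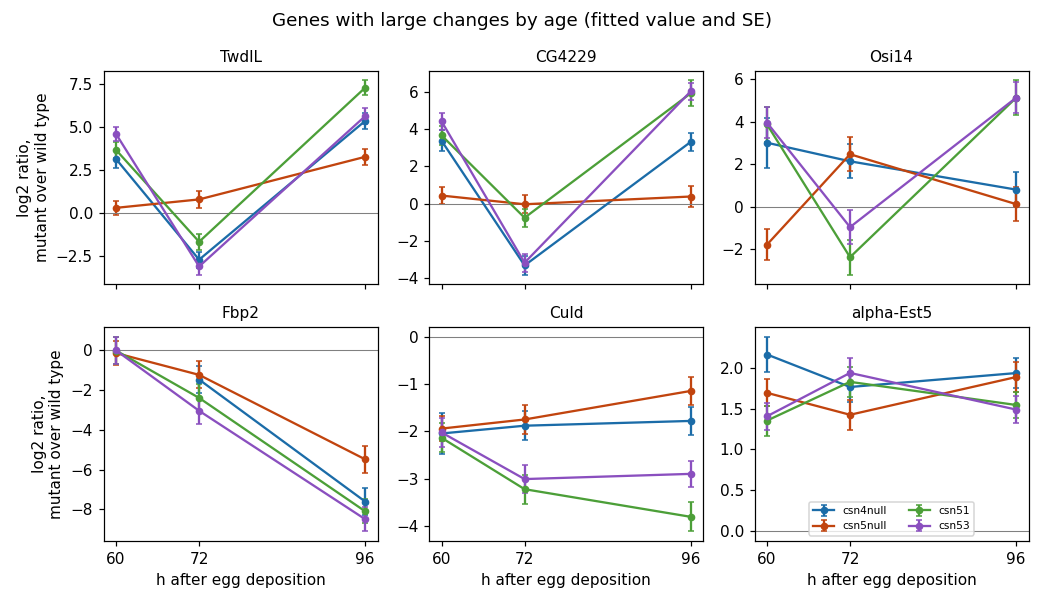
Fitted log2 ratio of mutant over wild type (points, with standard errors as bars) of 6 genes by age in h for the 4 genotypes, with no point for Fbp2 in csn4null at 60 h, where it was not tested. Fbp2 reaches -7.61, -5.49, -8.10 and -8.50 in csn4null, csn5null, csn51 and csn53 at 96 h, and alpha-Est5 lies between 1.35 and 2.16 in all 12 groups.

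The alleles csn51 and csn53 shared most, with 1286 features higher and 1277 lower in both at 60 h, where independent lists of these sizes would share 377 and 353. Across genes, which are not independent replicates, Pearson's r of their log2 ratios was 0.931 at 60 h, 0.741 at 72 h and 0.901 at 96 h. For csn4null and csn5null r was 0.151, 0.444 and 0.677 at these ages, with 345 features higher and 350 lower in both at 96 h against 88.3 and 78.5 for independent lists. Features called the same way in csn4null and csn5null numbered 110, 417 and 695 at these ages, 169 at 60 h without the 2 csn5null arrays whose CSN5 was near 0, and 668 and 1045 at 72 and 96 h without 3 csn5null arrays. Without these 3, csn5null at 72 h shared 378 features with csn51 and 385 with csn53, in place of 247 and 236. For csn4null and csn53 r was 0.637, 0.442 and 0.570, and for csn4null and csn51 0.580, 0.09 and 0.581. For csn5null r was 0.026, -0.0009 and 0.426 with csn51, and 0.0805, 0.1 and 0.448 with csn53. The 60 h values include csn5null replicate 5, which correlated best with an array of csn53. In csn51 and csn5null at 72 h 190 features were called in opposite directions, and independent lists would give 190. All 4 genotypes moved the same way for 79 features at 60 h, 101 at 72 h and 464 at 96 h. Without the 2 csn5null arrays whose CSN5 was near 0 the first 2 counts were 126 and 158. Whether genotypes shared wild-type RNA was not given in the sources used here. The covariance of the residuals of arrays of one age and number lay between -0.00326 and 0.00303 for each pair of genotypes, where the covariance of the log2 ratios reached 0.481. Only sharing by number could show in these residuals. Wild-type RNA common to all arrays of one age would be taken up by the group coefficients, so a part of the overlap from such sharing stays open.

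In all 12 groups 8 features were higher and 6 lower, and 10 of the 14 had a gene name. The genes higher throughout were alpha-Est5, an esterase gene, between 1.35 and 2.16, GstZ1 between 0.78 and 2.70, Idh, the isocitrate dehydrogenase gene, between 0.47 and 1.48, Oatp33Ea, an organic anion transporter gene, between 0.71 and 1.70, CG13603 between 0.33 and 1.18, and mth, a G protein-coupled receptor gene, between 0.31 and 1.10. The genes lower throughout were Culd, between -3.81 and -1.14, mTerf3, between -2.36 and -1.06, and Unc-115b and Unc-115a, related genes of actin-binding proteins, between -2.07 and -0.88 and between -1.32 and -0.53. These genes were named because they were called in every group, after their values were seen. A difference in genetic background from wild type cannot be told apart here from a shared effect of the mutations.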

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

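For the 2 csn5null arrays, the tests of entry order, of another group's sample and of the spread were chosen after the result was seen, as were the list, dye and scale tests of the 72 h pattern in csn51 and csn53, its 8 genes and the rule for control entries. Of 159 groups of values tested for 1 array far from the others, 31 met the criterion, where chance gives about 1 in 20. The criterion is the gap to the nearest array over the range of the group.

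The arrays labelled csn5null 72 h replicate 3 and csn5null 96 h replicate 3 had almost no fall of CSN5 (-0.32 and -0.01, gap 0.838 of the range at 72 h) and a median correlation with their own groups of -0.01 and 0.06 (gaps 0.953 and 0.948). Their highest correlation with an array of another group was 0.0362 and 0.335, below the lowest median correlation with its own group (0.516) of the arrays other than these 2 and csn5null 60 h replicate 5, which argues against a sample of another group with its values in order, and at 96 h the 0.335 also argues against values set against the wrong entries. Different entries of one gene correlated at -0.0455 and 0.152 on them, against 0.244 or more on the other 49 arrays, so at 72 h values set against the wrong entries may be the source, although duplicate spots, which could have stayed together, correlated at 0.598. The genes called one way in the other 11 groups had a median directed ratio of 0.033 and 0.114 on them, against 1.07 to 1.24 and 1.09 to 1.19 on the other arrays of those groups, which fits wild-type RNA in both channels at 96 h, where the SD of 0.344 was below the 0.488 to 0.495 of the other arrays, but does not decide it at 72 h, where wrong entries would give the same and the SD of 0.663 was above their 0.424 to 0.528. Both remain hypotheses, since duplicate spots at 96 h still correlated at 0.665, and whether these larvae differed biologically was not tested. On that 96 h array Srg2 was still at 1.27, and the 0.335 was with csn4null 96 h replicate 3. Wild-type RNA in both channels leaves these 2 values unexplained.

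In csn51 and csn53, TwdlL, TwdlF, TwdlW, Osi14, CG4229, ImpL1, dyl and CG3108 had lower ratios at 72 h than in the mean of 60 and 96 h, by a median of -6.87 and -4.70, but these 8 genes were picked because they showed it, so this size is no test, and on csn53 72 h replicate 4 their median was 3.22. Over both genotypes the swing of the arrays' medians was -5.22 with the mutant in Cy5 (95% interval -7.47 to -2.97, with 5 arrays at 72 h). It was -5.53 in Cy3 (-7.00 to -4.07, with 3 arrays at 72 h). Dye bias would give these 2 swings opposite signs, but the genes were picked on the same arrays, so the intervals are no independent evidence against it. After scaling the swing was -5.41 (-7.09 to -3.73) in csn51 and -4.40 (-6.54 to -2.26) in csn53. Scaling keeps the sign of every ratio, and the medians were above 0 on all arrays at 60 and 96 h and below 0 on most at 72 h. A strong swing therefore had to remain, so this could not test the scale of the arrays. Within each genotype dye bias was left open too, since csn51 had 1 Cy3 array at 72 h (-0.52) and the 2 Cy5 arrays of csn53 lay at -2.52 and 3.22. Of the control entries that by their names hold no fly gene, entries 1 and 2 of yeast and E. coli moved the same way, yeast control 1 with means of 0.18, -0.85 and 2.91 at 60, 72 and 96 h in csn51 and 0.74, -1.46 and 1.33 in csn53, while entries 3 and 4 moved less (yeast 4 with 0.18, 0.23 and 0.45 in csn51) and on csn53 72 h replicate 4 yeast control 1 was at -1.35 against the 3.22, so a cause outside the larval transcripts, shared with some controls, is neither shown nor excluded. Of the 4 measured genes of the larval cuticle list 3 (Cht5, Cpr49Ae and kkv) swung the same way past the threshold in both genotypes, as a shift in the timing of the moult against wild type would give, but levels in wild type by age were not measured here and this explanation stays open too.

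Called one way at all 3 ages in csn4null and at none in csn5null were 42 genes, 24 higher and 18 lower. Of these 7.14% (3 genes: CG8726, udd and Cyp6a13) were among the 94 measured genes nearest to CSN4, so most lay elsewhere. Genes farther along the chromosome of CSN4 can be linked to it and were not covered, so this cannot decide on linked variants as the whole cause. Variants near CSN4 as part of the cause could not be excluded, with an odds ratio of 3.63 (95% interval 0.705 to 11.8) and a one-sided Fisher's exact p = 0.0586. An effect of the loss of CSN4 apart from CSN5 stays open and was not tested.

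In csn5null at 60 h replicate 5, which correlated best with csn53 60 h replicate 2 (0.62), stood apart in its median correlation with its group (-0.02, gap 0.883), in CG8745 (3.60, gap 0.848), mTerf3 (-1.24, gap 0.913) and the median of cell cycle genes (-0.41, gap 0.871). The array labelled csn5null 72 h replicate 3 stood apart in Sirup (0.62, gap 0.888), CG7497 (-0.12, gap 0.912) and the COP9 median (-0.04, gap 0.879), and the one labelled csn5null 96 h replicate 3 in Srg2 (1.27, gap 0.864), Fbp2 (-0.01, gap 0.934) and the medians of proteasome (0.04, gap 0.845) and immunity genes (0.03, gap 0.864). In csn4null the gap was 0.833 for CSN4 and 0.840 for Cyp6a8 at 72 h, 0.931 for the correlation with the group at 72 h, and 0.894 for Rdh1 and 0.906 for the proteasome median at 96 h. In csn51 it was 0.864 for CSN5, 0.839 for the proteasome median and 0.851 for the correlation with the group at 60 h, 0.838 for Sirup at 72 h, and 0.716 for Fbp2 and 0.788 for the muscle median at 96 h. In csn53 it was 0.722 for TwdlL, 0.716 for Osi14 and 0.723 for the autophagy median at 60 h, and 0.764 for TwdlF, 0.827 for CARPB and 0.792 for Alp1 at 96 h.

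Tests of the difference between groups called 582, 655 and 304 features for csn4null minus csn5null at 60, 72 and 96 h, 12, 225 and 242 for csn51 minus csn53, and 2705, 1945 and 1810 for csn5null minus the mean of csn51 and csn53. Between 96 and 60 h they called 730 in csn4null, 2244 in csn51, 1940 in csn53 and 456 in csn5null. For 10 of these 13 differences only 1 split, the real one, reached the count, a share under 0.05 in each. That makes chance unlikely for each taken alone, but the shares were not adjusted over the 13 differences and chance is not excluded. The highest other count was 124 of 35 splits for csn4null minus csn5null at 72 h, 6, 81 and 143 of 100, 35 and 100 for csn51 minus csn53, and 1588, 1029 and 958 of 100 each for csn5null minus the mean. It was 264 of 35 splits in csn4null and 1816 and 816 of 100 each in csn51 and csn53 between ages. For csn4null minus csn5null at 96 h the numbers were taken to pair the arrays, from the residuals alone. Over all arrays of one age and number the estimated correlation was only 0.00646. Under that pairing the 8 splits that part all 4 pairs are too few for a share under 0.05, with a real count of 304 and a highest other of 24. The splits there that part 2 pairs or none gave at most 92 and 7. The splits do not make chance unlikely for csn4null minus csn5null at 60 h, where 6 of 56 splits gave as many and the highest other 1555. The same holds for 96 against 60 h in csn5null, where 6 of 100 did and the highest other was 1545. Both counts are several times the real one and point to a structure of the samples: the first of these splits sets csn5null 60 h replicate 5 with csn4null replicates 1 and 2, leaving csn4null replicate 3 with the other csn5null arrays, and the second sets it with csn5null 96 h replicates 1, 2 and 4.

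Within single groups the sign patterns of 3 to 5 arrays (4, 8 or 16) are too few for a share under 0.05. The real counts in csn4null at 60, 72 and 96 h were 1047, 1548 and 1940 and the highest others 82, 28 and 150. In csn51 they were 2904, 2134 and 3267 and the highest others 1085, 576 and 2390, and in csn53 3108, 1854 and 2506 with highest others 2029, 349 and 1530. In csn5null they were 491, 1099 and 1068 and the highest others 887, 1089 and 1144, where 2, 1 and 2 patterns reached the real count.

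Control entries, outside the comparisons, had group means above 1 in size with every array on one side of 0. Yeast control 1 had a mean of 2.91 (SD 1.19, n = 5) in csn51 at 96 h, -1.46 (n = 4) in csn53 at 72 h and 1.33 (n = 5) in csn53 at 96 h. Yeast control 2 had 2.72 (n = 5) in csn51 at 96 h and -1.15 (n = 4) in csn53 at 72 h. Yeast controls 3 and 4 had 0.12 and 0.45 in csn51 at 96 h. These are the genotypes and ages of that 72 h pattern.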

How the results depend on the processing

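Fits without the 2 csn5null arrays whose CSN5 was near 0, or without these and csn5null 60 h replicate 5, were chosen after the data were seen. Centring the arrays and leaving out the dye term moved none of the counts by over 1.5 times. No list called in the fit of all arrays turned its direction under the settings in which lists were tested. Lists were not tested entry by entry or with 1 array left out, and an estimated correlation cannot turn a direction. Unless the setting itself removes arrays or genes, the cause was not tested. Signal over background was not used here.

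With array weights the counts were 1603 in csn4null at 60 h, 3789 in csn53 at 96 h, 2502, 2021 and 1761 in csn5null at the 3 ages, 2250 and 604 for csn4null minus csn5null at 60 and 96 h, 42, 997 and 605 for csn51 minus csn53, 4190 for csn5null minus the mean at 60 h, and 1149, 3380 and 2077 for 96 against 60 h in csn4null, csn53 and csn5null. With arrays scaled they were 1511 in csn5null at 60 h, 1572 for csn4null minus csn5null at 60 h, 6 and 41 for csn51 minus csn53 at 60 and 96 h, and 1393 and 1108 for 96 against 60 h in csn51 and csn5null. With only the arrays of the groups compared and no dye term they were 78 in csn4null at 60 h, 959 in csn53 at 72 h, 1 and 39 in csn5null at 72 and 96 h, 278 and 149 for csn4null minus csn5null at 72 and 96 h, 7, 21 and 46 for csn51 minus csn53, and 229 for 96 against 60 h in csn5null. With a value on every array csn51 minus csn53 at 96 h gave 151.

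Without 3 csn5null arrays the counts were 1064 and 1688 in csn5null at 60 and 96 h, 1675 and 564 for csn4null minus csn5null at 60 and 96 h, 459 and 396 for csn51 minus csn53 at 72 and 96 h, 1517 for 96 against 60 h in csn5null, and 180 features shared by all 4 genotypes at 72 h. Without 2 they were 360 for csn51 minus csn53 at 72 h, 988 for 96 against 60 h in csn5null, and 126 and 158 shared at 60 and 72 h.

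With an estimated correlation the number of lists called fell from 4, 2 and 7 to 1, 0 and 0 in csn4null, from 5, 3 and 6 to 0, 1 and 0 in csn51, from 6, 4 and 3 to 1, 1 and 0 in csn53, and in csn5null from 4 and 5 to 1 and 2 at 72 and 96 h. Over all groups 42 list calls were lost. The 1 list left in csn4null was the COP9 list, which holds the mutated gene CSN4. The number of lists called was 4 in csn4null at 96 h with array weights, and 2 there and in csn5null at 72 h with only the arrays of the groups compared and no dye term.

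Lists that gained a call in fits of their own arrays without a dye term, beyond those in the report, were larval cuticle (adjusted p = 0.0274) at 60 h and oxidative stress (adjusted p = 6.1e-06) at 72 h in csn4null, DNA damage (0.047) at 60 h and autophagy (0.0211) at 72 h in csn51, larval cuticle (0.0173) in csn53 at 60 h, and heat shock (0.0396) and cell cycle (0.0233) in csn5null at 96 h. With array weights they were cuticle (0.0424) at 60 h and cell cycle (0.0453) at 96 h in csn53 and autophagy (0.0375) in csn5null at 60 h, without 3 csn5null arrays the last (0.0258), and over all arrays without a dye term cuticle in csn53 at 60 h (0.0444) and oxidative phosphorylation in csn5null at 72 h (0.047).

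Prosalpha5 in csn5null at 72 h turned from -0.57 to 0.00603 with array weights, 0.0815 without 2 and 0.0820 without 3 csn5null arrays, and lay between -0.84 and 0.0842 with 1 array left out. Orc4 in csn4null at 60 h lay between -0.46 and 3.90 with 1 array left out, the former without replicate 1. Counting each named gene, comparison and array left out as a result, 482 results lost their call, 2 turned direction and 3465 kept their status.

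With 1 array left out the count ranged from 232 to 848 in csn4null at 60 h, 300 to 886 and 582 to 1423 in csn5null at 60 and 96 h, 150 to 1375 and 182 to 321 for csn4null minus csn5null at 60 and 96 h, 7 to 13 and 62 to 368 for csn51 minus csn53 at 60 and 72 h, and 401 to 610 and 221 to 953 for 96 against 60 h in csn4null and csn5null.

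With arrays of one age and number as a random block, for the pairing, csn4null minus csn5null called 315 features at 96 h in place of 304, and no call printed in the report changed.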

Other observations

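The genes and entries described here were chosen after their values were seen, and no explanation of them was tested.

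In csn4null at 72 h the cuticle protein gene Cpr49Ae fell by 3.22 (adjusted p = 1.8e-09). The prophenoloxidase gene PPO3 rose by 1.06 in csn51 at 60 h and was lower at -1.30 at 96 h, with limma adjusted p-values of 4.0e-05 and 9.3e-08. In csn53 it rose by 1.22 at 60 h (adjusted p = 6.0e-07), and PPO1 was lower at -0.90 at 96 h (adjusted p = 0.000106).

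Among entries with no gene listed, 5 were higher in csn51 and csn53 at every age, with lowest group values of 3.16, 3.07, 2.99, 2.62 and 2.02. In csn4null and csn5null the same 5 lay between -0.75 and 0.67.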
